A study of Homo sapiens with 26 samples.

How the data were processed

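RNA was sequenced from 13 primary breast tumors and 13 distal metastases, extracted from formalin-fixed, paraffin-embedded tissue and prepared with an exon-capture library kit, per the labels' protocols. The submitters' processing notes name CASAVA, Bowtie2, Subread, featureCounts and DESeq2 and the genome build hg19, with versions, parameters, strand setting and gene annotation not given in the sources used here. The deposited values are variance-stabilized expression on a log2 scale, in a single table of 20581 genes by 26 libraries, with DESeq2 named by the submitters' processing notes. Their lowest value was 4.338 and their highest 22.28. Inverting the transformation gave whole reads for 100% of 534612 values (tolerance 0.01 reads), and these reads gave the depth of each library. No unique molecular identifiers are recorded, so reads are not independent molecules and depth gives an upper limit on precision. Coordinates are not printed, because the reference used here for gene names is another build.

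The columns of the table carry a tumor type and a pair number. The 13 pair numbers run from 1 to 17 with gaps, whereas the sample titles run from 1 to 13, so the name of a column gave its group and pair but not a titled sample, and no organ was assigned to a metastasis column, neither from the order of the columns nor from marker values. Tests by organ, which were planned for 4 organs with 2 metastases each, were therefore not run. The pairing comes from the shared number and from the design text, which says that the tumors are paired. A metastasis correlated above 0.1 with its same-numbered primary in all but 1 of 13 pairs, pair 8 (0.04). Each pair was taken as separate from the others, and 0 columns were left unmatched.

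Of the table, 19 sex-linked genes were left out. Genes entered the tests if their mean over 26 libraries was at least 1 above the lowest value, which left 14910 and removed 5652. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model with the pair as a fixed block, empirical Bayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). A difference of variance-stabilized values is close to a log2 fold change at high expression and smaller than it at low expression. CECR2, the balance of M2-type over M1-type genes and list means were tested with a two-sided exact sign-flip permutation of the pair differences (all sign patterns, smallest possible p = 0.000244). Gene lists were tested with limma camera (preset correlation 0.01, and again with an estimated correlation) and limma fry, over the 32 of 36 lists with at least 5 tested members; 666 of 668 list entries were matched, 14 of them by an older symbol. The blood, ovary, stomach and esophagus lists had fewer tested members and were not tested. Correlations and the similarity of pairs used 100000 resamples. The tests were checked on simulated data with known changes. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.

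The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule names CECR2, the 10 largest rises and 10 largest falls past the threshold with the same direction in at least 11 of 13 pairs, up to 4 members with the smallest p of each list described, and the markers ESR1, PGR, ERBB2, MKI67, CD274, CD163, MRC1 and CD8A; its part on organ markers by site could not be applied. Some genes that the rule takes are not reported here, though they stay in the counts and list means. Alternatives covered the block, the filter, the scaling, the trend, library weights, single pairs left out and the list test. Added after seeing the data were limma voom on the recovered reads, log2 of RPM plus 1 for CECR2, the sign-flip test of list means, and fits without 2 pairs with high liver markers or without 3 pairs with a library under 10 M reads.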

Results

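Gene expression was measured by RNA sequencing in 13 primary breast tumors and 13 distal metastases, each metastasis paired with a primary tumor. RNA came from formalin-fixed, paraffin-embedded tissue, a clinical archive material in which RNA is fragmented, and libraries were enriched for coding exons by capture. The metastases came from 9 organs. Values were variance-stabilized expression levels on a log2-like scale, written below as log2 units. Whole reads recovered from these values came to a median of 19.4 M per primary library (6.6 to 45.7 M) and 20.0 M per metastasis library (5.2 to 41.3 M). The metastasis library was the deeper in 7 of 13 pairs (two-sided exact sign-flip p = 0.95).

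The first question was whether CECR2, the acetyl-lysine reader named in the title of the series, differed between metastases and primary tumors. CECR2, a bromodomain protein of chromatin remodeling complexes, was at 6.98 ± 1.40 log2 units in primary tumors and 8.38 ± 1.76 in metastases (SD, n = 13 each). It rose by 1.40 ± 1.40 log2 units (SD over 13 pairs). It was higher in the metastasis in 12 of 13 pairs (two-sided exact sign-flip p = 0.00586). Median normalized reads of CECR2 were 76.1 in primary tumors and 185.5 in metastases, with 1 to 4290 reads per library. The variance-stabilized scale compresses differences at low expression, and the geometric mean ratio of normalized reads was 3.94-fold, a value that weighs libraries with few reads as much as the others. On the scale of log2 (RPM + 1), chosen after seeing the data, the mean CECR2 difference was 1.57 (two-sided exact sign-flip p = 0.00391). In the limma fit of all genes CECR2 did not pass the threshold (log2 difference 1.40, SE 0.35, limma adjusted p = 0.0611). Without pair 13, in which CECR2 was lower in the metastasis, the log2 difference was 1.65 and the limma adjusted p = 0.0321, within a range of 0.0231 to 0.441 over all settings tried. CECR2 gave the series its title, so its rise in these tumors is not independent evidence of its direction.

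**Figure D1:**
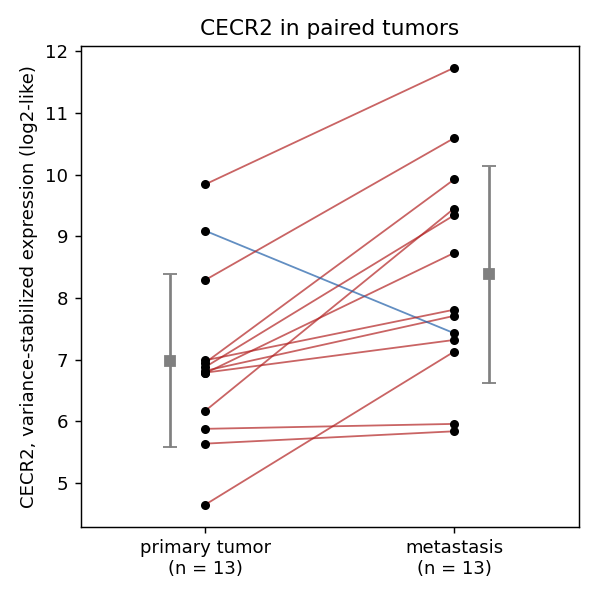
CECR2 expression (variance-stabilized, log2-like units) in 13 primary tumors and their paired metastases. Black points are tumors, lines join the tumors of a pair (red where the metastasis was higher, blue where lower), and gray squares with bars give the mean ± SD of 6.98 ± 1.40 and 8.38 ± 1.76; 12 of 13 lines go up.

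The second comparison asked which genes differed between metastases and primary tumors. The 10 largest rises included UNC80, a subunit of the sodium leak channel complex of neurons (log2 difference 1.85, SE 0.32, higher in 12 of 13 pairs), and ASXL3, a Polycomb-associated chromatin protein (1.72, SE 0.33, 13 of 13 pairs). FADS2, the delta-6 fatty acid desaturase, rose by 1.45 (SE 0.25) in 12 of 13 pairs. The 10 largest falls included KRT14, a keratin of basal and myoepithelial cells (log2 difference -3.72, SE 0.64, lower in 12 of 13 pairs), SFRP2, a secreted WNT modulator of fibroblasts (-3.35, SE 0.77, 12 pairs), and FABP4, the adipocyte fatty acid binding protein (-2.43, SE 0.56, 11 pairs). CD3E, a chain of the T cell receptor complex, fell by 2.27 (SE 0.47) in 11 of 13 pairs. CXCL9, an interferon-induced chemokine that attracts T cells, fell by 2.19 (SE 0.40) in 12 of 13 pairs.

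Further genes among the largest rises were RAP1GAP (1.48), a GTPase activating protein for RAP1, TTLL7 (1.47), a tubulin polyglutamylase, PLA2G4F (1.21), a phospholipase, RGN (1.20), a calcium-binding lactonase, ARHGEF37 (1.20) and MTUS2 (1.09), each in at least 11 of 13 pairs. The other large falls were IGLL5 (-4.04), CCDC80 (-2.53), the membrane metalloendopeptidase MME (-2.50), the chemokine CXCL14 (-2.20) and the stromelysin MMP3 (-2.19), each in at least 11 of 13 pairs. IGLL5 overlaps immunoglobulin lambda segments and KRT14 resembles other type I keratins closely, so the share of reads that belonged to each is uncertain. These 20 genes had limma adjusted p from 0.0195 for MMP3 to 0.0466 for SFRP2.

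Across 14910 tested genes, 23 rose and 141 fell in metastases at a limma adjusted p under 0.05, and 2287 genes had an unadjusted p under 0.05. The split between rises and falls depended on the fit: 129 rose and 298 fell by limma voom on recovered reads, chosen after seeing the data, 88 rose and 334 fell with library quality weights, and 0 rose and 26 fell without the pairing as a block. Of the 164 genes, 12 rose and 112 fell by at least 1 log2 unit. The median log2 difference of all tested genes was 0.03, and 45.6% of them had lower estimates. In simulated data with 13 pairs and 200 changed genes, the test recovered 60.5% of 2-fold, 95.5% of 4-fold and 99.5% of 8-fold changes. The changed genes were drawn only from those with a mean more than 3 above the lowest value, and genes were simulated independently. These rates therefore do not cover tested genes of lower expression or genes that vary together. The 26 genes without the block were all among the 164. The count depended on single pairs: it was 24 without pair 1, 7 without pair 5, 49 without pair 6, 46 without pair 7, 94 without pair 8, 5 without pair 9, 106 without pair 12, 97 without pair 13, 279 without pair 15 and 33 without pair 17. Each of the 164 genes kept its direction in all of these fits. They were picked in the same data, so leaving out 1 pair could hardly reverse them, and this adds no support.

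**Figure D2:**
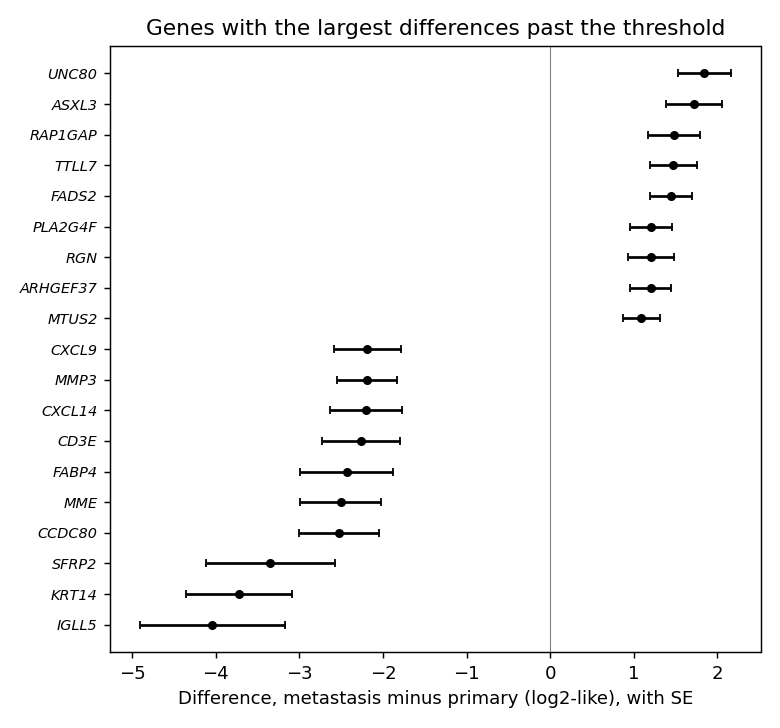
Difference between metastasis and primary tumor (log2-like units, points) with its standard error (bars) for genes with the largest rises (9 shown) and the 10 largest falls past the threshold over 13 pairs. The differences run from -4.04 for IGLL5 to 1.85 for UNC80.

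Receptor and immune markers chosen in advance were examined alone. ESR1, the estrogen receptor, had a log2 difference of -1.32 (SE 0.31) and was lower in the metastasis in 12 of 13 pairs (limma adjusted p = 0.0515). ERBB2, the HER2 receptor, had a difference of 0.71 (SE 0.24, higher in 10 of 13 pairs, limma adjusted p = 0.159), and PGR, the progesterone receptor, -1.05 (SE 0.51, lower in 10 pairs, adjusted p = 0.334). The proliferation marker MKI67 had a difference of -0.37 (SE 0.40), which was -0.03 without pair 8 and -0.64 without pair 1, and the checkpoint ligand CD274 of -0.65 (SE 0.34). CD8A of cytotoxic T cells was at -1.33 (SE 0.40, lower in 11 pairs) and the macrophage scavenger receptor CD163 at -0.69 (SE 0.32). None of these 7 markers passed the threshold in the limma fit, and MRC1 is not analysed here. ESR1 passed without pair 11 (log2 difference -1.51, limma adjusted p = 0.0196) and without pair 15 (-1.05, 0.0312), and CD8A passed without pair 15 (-1.60, 0.0321). Over all settings tried the limma adjusted p ran from 0.0196 to 0.854 for ESR1 and from 0.0321 to 0.32 for CD8A.

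The third comparison asked whether immune genes moved together, as the title of the series names macrophage polarization and immune suppression. T cell genes fell in metastases: all 21 tested T cell genes had lower estimates, with a mean of -1.33 ± 1.37 log2 units (SD over 13 pairs, lower in 11 of 13 pairs). The estimated correlation between these genes was 0.75, so their estimates are not independent, and with it the list did not pass by camera (adjusted p = 0.0929). Of these genes, 3 passed over all genes tested and 19 adjusted over the list alone, among them CD3E and the signaling adaptor SH2D1A (-1.65, SE 0.32). Cytotoxic and NK cell genes fell by 0.81 ± 0.78 (11 of 13 pairs), with 2 of 12 passing over all genes, namely EOMES (-1.16, SE 0.25) and GZMK (-1.23, SE 0.26), and 8 adjusted over the list alone. Dendritic cell genes fell by 1.21 ± 0.87 (12 of 13 pairs), led by the lectin CLEC10A (-1.51, SE 0.29), the IgE receptor chain FCER1A (-1.23, SE 0.24) and the cytokine receptor FLT3 (-1.34, SE 0.28), with 3 of 8 passing over all genes and 8 adjusted over the list alone. With an estimated correlation the dendritic cell list passed by camera (adjusted p = 0.039) and the cytotoxic and NK cell list did not (adjusted p = 0.0929).

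Genes of the macrophage lists were lower as well, though none of the pan-macrophage, M1-type and M2-type lists passed by camera with an estimated correlation (adjusted p = 0.0929 for each). Libraries were made from whole tissue, so the cells that expressed these genes are not known, and the lists do not measure macrophage state alone. The pan-macrophage list fell by 0.86 ± 0.96 log2 units in 11 of 13 pairs, with CSF1R, the receptor for macrophage colony stimulating factor, at -1.26 (SE 0.24). Of its genes, 1 of 16 passed over all genes and 14 adjusted over the list alone. The M1-type list fell by 1.06 ± 0.90 (11 pairs; 3 of 13 genes over all genes, 9 adjusted over the list alone), with CXCL9, CCL5 (-1.40, SE 0.30) and IDO1 (-1.44, SE 0.33), a tryptophan-degrading enzyme. The M2-type list fell by 0.62 ± 0.64 (11 pairs; 4 of 14 genes over all genes, 5 adjusted over the list alone), with F13A1 (-1.83, SE 0.38), TGFB1 (-0.77, SE 0.15), STAB1 (-0.91, SE 0.19) and CD209 (-1.53, SE 0.33). The median of its genes was -0.56, and -0.37 without pair 13.

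Genes of immune regulation and antigen display followed the same direction. The immune checkpoint and suppression list fell by 0.74 ± 0.45 log2 units in 13 of 13 pairs, with the ectonucleotidase ENTPD1 at -1.22 (SE 0.22) and the inhibitory receptor CTLA4 at -1.42 (SE 0.33). Of its genes, 4 of 14 passed over all genes and 8 adjusted over the list alone. Among these 4, TGFB1 is also in the M2-type list and IDO1 in the M1-type list, so these lists are not separate evidence. All 21 antigen presentation genes had lower estimates (mean -1.03 ± 0.95, 12 of 13 pairs), with 5 passing over all genes and 21 adjusted over the list alone. Those named by the rule were CD74, the class II invariant chain (-1.59, SE 0.28), its regulator CIITA (-1.78, SE 0.39), HLA-DRB1 (-1.25, SE 0.27) and HLA-DQA1 (-1.75, SE 0.39). Reads of HLA genes are shared between near-identical copies, so their split is uncertain. Interferon response genes fell by 1.01 ± 1.25 (10 of 13 pairs), led by MX2 (-1.28, SE 0.27), with 1 of 24 passing over all genes and 18 adjusted over the list alone. NF-kB response genes fell by 0.56 ± 0.59 (11 of 13 pairs), with 0 of 21 passing over all genes by limma and 9 adjusted over the list alone. With an estimated correlation the checkpoint list passed by camera (adjusted p = 0.039), whereas antigen presentation and NF-kB genes (adjusted p = 0.0929) and interferon genes (adjusted p = 0.105) did not.

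Over 32 lists, limma camera with a preset correlation of 0.01 called 17 lower and 5 higher, with adjusted p of 2.0e-17 for T cells, 3.2e-10 for cytotoxic and NK cells, 1.2e-09 for dendritic cells, 1.6e-11 for pan-macrophage, 1.0e-09 for M1-type, 3.6e-07 for M2-type, 5.0e-10 for checkpoint, 1.8e-18 for antigen presentation, 5.8e-15 for interferon and 1.1e-08 for NF-kB genes. These preset-correlation values overstate the evidence: with labels swapped within pairs, the median of the other splits was already 14 lists called. With an estimated correlation, camera called 3 lists, all lower: checkpoint, dendritic cell and mesenchymal transition genes, each at adjusted p = 0.039 with an estimated correlation. Limma fry, which asks whether genes of a list move one way on balance, called 13 lower and 1 higher. An exact sign-flip test of the list mean over the 13 pairs, chosen after seeing the data, called 15 lower and 1 higher. Its adjusted exact p was 0.00781 for checkpoint, 0.013 for dendritic cell, 0.0156 for T cell, cytotoxic and NK cell, M1-type, M2-type and antigen presentation, 0.0195 for pan-macrophage, 0.0221 for NF-kB and 0.0257 for interferon genes.

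Stromal and epithelial genes were compared in the same way. Fibroblast and matrix genes fell by 1.43 ± 1.57 log2 units in 11 of 13 pairs, with the protease CTSK (-1.93, SE 0.33) and SFRP2 passing over all genes (2 of 24) and 16 adjusted over the list alone (camera adjusted p = 1.4e-15, and adjusted p = 0.0929 with an estimated correlation). Mesenchymal transition genes fell by 0.72 ± 0.48 in 12 of 13 pairs (camera adjusted p = 9.2e-10), with 1 of 20, MMP3, passing over all genes and 15 lower and 1 higher adjusted over the list alone. Basal and myoepithelial genes fell by 1.35 ± 1.74 in 10 of 13 pairs (camera adjusted p = 2.0e-07, and adjusted p = 0.183 with an estimated correlation), with KRT14 passing over all genes and 9 of 17 adjusted over the list alone. Their median was -1.27, and -0.78 without pair 8, in which the list was at -5.73. Epithelial junction genes rose by 0.50 ± 0.52 in 12 of 13 pairs (camera adjusted p = 4.6e-07, and adjusted p = 0.0929 with an estimated correlation), with 0 of 18 passing over all genes by limma and 6 adjusted over the list alone, among them the splicing factor ESRP2 (0.69, SE 0.19) and the transcription factor GRHL2 (0.76, SE 0.26). Immediate early genes fell by 0.60 ± 0.73 in 12 of 13 pairs (camera adjusted p = 1.1e-06, and adjusted p = 0.1 with an estimated correlation), with 0 of 20 passing over all genes and 3 adjusted over the list alone. In the sign-flip test of list means the adjusted exact p was 0.0234 for fibroblast and matrix, 0.013 for mesenchymal transition, 0.0221 for basal and myoepithelial, 0.0156 for epithelial junction and 0.0302 for immediate early genes.

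Luminal and estrogen receptor genes had a mean of -0.38 ± 0.65 log2 units (10 of 13 pairs lower; camera adjusted p = 0.00212, and adjusted p = 0.246 with an estimated correlation), with 0 of 26 passing over all genes and 1, ESR1, adjusted over the list alone. The luminal list passed the sign-flip test (adjusted exact p = 0.0405), and the other lists of this paragraph did not. B and plasma cell genes were at -1.35 ± 2.15 (9 pairs lower; camera adjusted p = 1.1e-06, and adjusted p = 0.229 with an estimated correlation), with 0 of 12 passing over all genes and 2 adjusted over the list alone. Adipocyte genes were at -1.0 ± 1.94 (8 pairs lower; camera adjusted p = 1.8e-05, and adjusted p = 0.276 with an estimated correlation), with ADIPOQ (-2.64, SE 0.53) and FABP4 passing over all genes and 3 of 13 adjusted over the list alone. ERBB2 amplicon genes were at 0.36 ± 0.71 (9 pairs higher; camera adjusted p = 0.018, and adjusted p = 0.326 with an estimated correlation), with 0 of 7 passing over all genes and 2, ERBB2 and GRB7, adjusted over the list alone. Hypoxia and glycolysis genes were at 0.24 ± 0.38 (11 pairs higher; camera adjusted p = 0.0298, and adjusted p = 0.326 with an estimated correlation), with 3 higher and 1 lower of 18 adjusted over the list alone, including VEGFA (0.83, SE 0.21). Oxidative phosphorylation genes were at 0.18 ± 0.36 (10 pairs higher; camera adjusted p = 0.00111, and adjusted p = 0.382 with an estimated correlation), with 0 of 28 passing by either adjustment. The calls of 4 of these lists by camera with the preset correlation depended on single pairs, and list medians moved with them: from 0.25 to 0.08 for the ERBB2 amplicon without pair 12, from -0.33 to -0.15 for luminal genes without pair 15, and from 1.11 for liver markers to 0.39 without pair 11 and 0.42 without pair 12. The median of hypoxia genes moved from 0.21 to 0.35 without pair 13, and that of oxidative phosphorylation genes from 0.18 to 0.12 without pair 8 and 0.30 without pair 14. The hypoxia call ended without pair 2, 7, 12 or 14 (camera adjusted p from 0.0579 to 0.117, 0.0056 to 0.326 over all settings). The ERBB2 amplicon call ended without pair 12 or 15 (0.124 and 0.0525, 0.00169 to 0.326 over all settings) and the luminal call without pair 15 (0.0815, 0.000505 to 0.246 over all settings). Liver markers, at 1.12 ± 2.73 (10 pairs higher; camera adjusted p = 0.000109, and adjusted p = 0.401 with an estimated correlation), lost their call without pair 11 or 12 (0.182 and 0.19).

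Endothelial genes, markers of blood vessel lining, did not pass by camera (mean 0.02 ± 0.91 log2 units, 9 of 13 pairs lower, median -0.05, camera direction up), nor did smooth muscle and pericyte genes (0.14 ± 1.16) and proliferation genes (0.06 ± 1.32, 7 of 13 pairs lower). Mast cell genes were at -0.38 ± 0.89 and breast identity genes at -0.31 ± 1.31. Acetyl-lysine reader and bromodomain genes, the family of CECR2, had a mean of -0.03 ± 0.24, a median of 0 and a camera direction of up. Of its members, 2 of 38, SP110 (-1.26, SE 0.27) and SP100 (-1.09, SE 0.24), fell over all genes, and CECR2, SP110, SP100 and SP140 were among 5 that passed adjusted over the list alone. Brain markers were at 0.43 ± 1.28, lung markers at 0.41 ± 1.24, skin markers at 0.08 ± 0.60 and skeletal muscle markers at -0.08 ± 0.81, with a median of 0.26 for the last. None of these lists passed by camera with either correlation, by the directional fry test or by the sign-flip test. The fry test for changes either way passed for the acetyl-lysine reader list alone (fry mixed adjusted p = 0.000465), with 19 members estimated higher and 19 lower. Without pair 8 proliferation genes passed upward by camera (median 0.32, camera adjusted p = 9.3e-05, range 9.3e-05 to 0.963 over all settings). Without pair 9 breast identity genes passed downward (median -0.50, camera adjusted p = 0.019, range 0.019 to 0.701). Brain markers passed without pair 8, 9, 11 or 12 and lung markers without pair 2 or 5. Each of these lists was far higher in 1 metastasis: brain markers at 4.36 in pair 7 and lung markers at 3.96 in pair 14. Without pair 7 the median of brain markers was 0.07 and the camera direction turned down (camera adjusted p = 0.914).

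**Figure D3:**
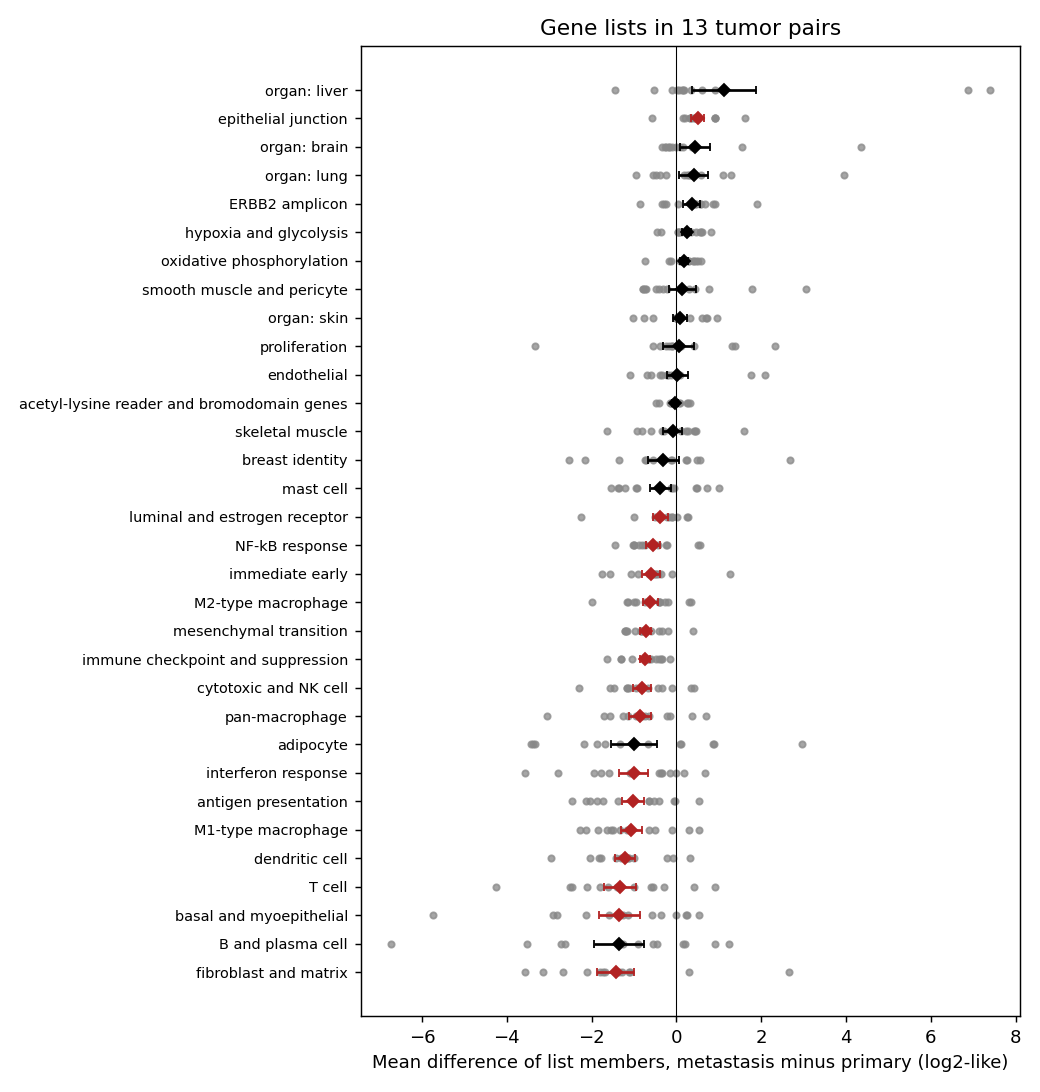
Mean difference of each gene list between metastasis and primary tumor (log2-like units) in 13 pairs. Gray points are pairs and diamonds with bars are means ± SE, red where the adjusted exact sign-flip p was under 0.05 (16 of 32 lists); the checkpoint list lies below 0 in 13 of 13 pairs.

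The balance of macrophage genes was compared because the series title names macrophage polarization. The mean of 14 M2-type genes minus that of 13 M1-type genes was -0.22 ± 0.92 log2 units in primary tumors and 0.22 ± 0.40 in metastases (SD, n = 13 each). The balance was higher in the metastasis in 10 of 13 pairs. The mean difference of 0.45 ± 0.96 (SD over 13 pairs) was not told apart from 0 (two-sided exact sign-flip p = 0.117). Without pair 6 the difference was 0.29.

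CECR2 differences were then set against those of 9 immune lists over the 13 pairs. The M2-type list had the largest correlation with CECR2 (Pearson r = 0.65, permutation p = 0.0151, adjusted p = 0.136 over the 9 relations in this permutation test; Spearman rho = 0.45, permutation p = 0.131). Without the 2 pairs farthest from the median CECR2 difference, r was 0.27 (permutation p = 0.416). Leaving out pairs by their CECR2 difference narrows its range, which can itself lower r. The drop therefore does not settle whether the M2-type relation rests on those pairs. The other 8 relations had r from -0.14 for T cells to 0.32 for interferon response, and 0 of 9 passed after adjustment in the permutation test (1 at an unadjusted p under 0.05).

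Metastases resembled their own primary tumors. Over the 5000 most variable genes the mean correlation of a metastasis with its own primary was 0.41 and with the other primaries -0.03 (difference 0.45, one-sided permutation p = 1e-05, the smallest that the permutations can give). Of 13 metastases, 9 matched their own primary best, and 1 pair, pair 8, had a correlation under 0.1 (0.04). Pair 8 also had the basal list at -5.73, the proliferation list at -3.34 and the blood list at 5.63. Its metastasis library held 5.2 M reads and its primary library 1 read of CECR2. Without pair 8 the mean CECR2 difference was 1.31 (exact sign-flip p = 0.0117). Why this pair differed was not tested. Metastases were at a mean distance of 1.28 log2 units per gene from each other and primary tumors of 1.18; the difference of 0.102 was not larger than swaps of labels within pairs give (two-sided exact p = 0.0894, over every swap).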

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

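Fits on recovered reads, without pairs with high liver markers or shallow libraries, and the sign-flip test of list means were chosen after seeing the data. The count of 164 genes became 26 with no block for the pairing, 441 with the pairing as a random effect, 27 with no filter on low values, 422 with library quality weights, 69 without pairs with a library under 10 M reads and 427 by limma voom on recovered reads, and ran from 5 to 279 without each pair in turn. The cause was not tested. Of the 164 genes, 150 were shared with the random effect fit and 160 with voom. Without the 2 pairs with high liver markers, 201 genes passed, 127 of them shared. The 20 genes with the largest differences kept their direction in all 490 recomputed values, which their selection in the same data made likely, and passed in 312. ESR1 also passed with the stricter filter, with median centring and without the pairs with high liver markers, and CD8A with the random effect. The count of 22 lists became 3 by camera with an estimated correlation and 14 by fry. CECR2 in the limma fit of all genes passed with library quality weights (1.383) and by voom (1.921). It ran from 1.243 to 1.654 without each pair, and of these fits passed only without pair 13. It was 1.19 without pairs with a library under 10 M reads (limma adjusted p = 0.18) and 1.212 without the pairs with high liver markers (limma adjusted p = 0.16). The exact test of CECR2 kept its side in every setting, as did the M2 to M1 balance, the similarity and the spread. With no block, 16 of the 20 genes lost their call, as did the ERBB2 amplicon and hypoxia lists, and brain and lung markers gained one by camera; no other list, named gene or marker changed its call.

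Of the 22 lists called by camera, 560 of 609 recomputed values kept direction and call, 48 lost the call and 1 changed direction: liver markers without the pairs with high liver markers (median -0.042). Of the 10 lists not called, 31 of 271 recomputed values changed direction and 24 gained a call by camera, and the cause was not tested. The calls gained were 13 for brain markers, 7 for lung markers, 2 for mast cell genes (adjusted p = 0.0161 with no filter and 0.032 with library quality weights, within 0.0161 to 0.541) and 1 each for proliferation and breast identity genes. With no filter 28 lists passed, 10 of them higher. Acetyl-lysine reader genes had medians of -0.003 with no block, with a random effect, with no filter and without trend, -0.022 with median centring, -0.018 without liver pairs, 0.002 by voom and from -0.017 to 0.03 without each pair. Their mean was -0.03. The median of skin markers was 0.028 with no filter (from -0.041 to 0.201 without each pair). That of smooth muscle genes was -0.171 with the stricter filter and -0.102 without shallow pairs (from -0.222 to 0.122 without each pair). Endothelial genes had medians of -0.177 with weights and -0.186 without shallow pairs (from -0.188 to 0.057 without each pair). Proliferation genes had a median of -0.028 without liver pairs (from -0.109 to 0.321 without each pair). Skeletal muscle markers had a mean of -0.08 and a median of 0.26, and the median ran from 0.017 to 0.317 without each pair. The median of brain markers ran from 0.074 to 0.534 without each pair.

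CECR2 correlations changed sign, none past the threshold, as follows. In metastases alone r was 0.286 with T cells, 0.239 with checkpoint and 0.438 with antigen presentation genes. In primary tumors alone r was -0.514 with NF-kB, -0.3 with pan-macrophage, -0.448 with M1-type, -0.25 with cytotoxic and -0.095 with interferon genes. With quantile normalization r was -0.035 with M1-type and -0.007 with cytotoxic genes, and without the 2 farthest pairs 0.102 with checkpoint and 0.075 with antigen presentation genes. Planned fits without the brain, liver, lung or ovary pairs and the organ marker tests were not run, because no column name matched a titled sample with its organ. Depth limits genes with few reads most: libraries held 5.2 to 45.7 M reads.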

Other observations

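All tests in this part were chosen after the results were seen. Antigen presentation genes were divided into class II, which display peptides to helper T cells, and class I. The list members PSMB8, PSMB9 and PSMB10 were put in neither class. The 9 class II genes, among them CD74, CIITA and HLA-DRA, fell by 1.36 ± 1.19 log2 units (SD over 13 pairs, lower in 12 of 13 pairs, exact sign-flip p = 0.00195), and 9 class I genes, among them B2M and TAP1, fell by 0.80 ± 0.94 (9 of 13 pairs, exact sign-flip p = 0.0132). The hypothesis was that class II falls further. The class II minus class I difference was -0.56 ± 0.84 (below 0 in 9 of 13 pairs, exact sign-flip p = 0.0337), so class II genes may have fallen further. No explanation of this difference was tested.

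Organ markers stood high in single metastases, given here as values because no column name gave an organ. The liver list was 7.21 and 6.85 log2 units above the own primary in 2 metastases, with 27 of 27 members at least 1 higher in each. In 1 metastasis each, the brain list was 3.97 higher (20 of 22 members), the lung list 4.67 (14 of 15), the ovary list 2.81 (12 of 14) and the stomach list 9.92 (10 of 10). The next highest values were 0.75 for liver, 0.88 for brain, 1.85 for lung, 1.43 for ovary and 1.22 for stomach markers. The blood list, with hemoglobin genes, ranged from -1.44 to 5.63 over the 13 pairs, with 1.09 as its next highest value, and the esophagus list from -1.02 to 0.64.

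Chance was examined by swapping primary and metastasis labels within pairs, with 100 splits drawn including the real one. Only the real split, 1 of 100, gave as many as 164 genes, and the highest other gave 10. This argues against chance for the count of genes, but only to the 1 in 100 that these splits resolve. The count fell to 5 without pair 9 and 7 without pair 5, fits for which no swaps were drawn. By camera with the preset correlation, 6 of 100 splits gave as many as 22 lists and the highest other gave 25, so chance was not excluded for that count of lists. The median of the other splits was 14 lists, so a call by camera with the preset correlation is weak evidence for a list.

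Immune genes fell by 0.98 ± 0.72 log2 units over 140 genes (SD over 13 pairs, 12 of 13 pairs lower, exact sign-flip p = 0.00122). The set joined the macrophage, T cell, cytotoxic and NK cell, dendritic cell, checkpoint, antigen presentation and interferon lists, chosen with their results known. Left out were the B and plasma cell and mast cell lists, which did not pass the sign-flip test (adjusted exact p = 0.0556 and 0.212), and the NF-kB list, which did. The p of the set is therefore not independent support for the fall. Shallower metastasis libraries are argued against by a mean immune difference of -1.08 ± 0.58 in the 7 pairs with a deeper metastasis library (exact sign-flip p = 0.0156). At equal adipocyte and basal list levels the immune difference was -1.25 (95% interval -2.0 to -0.51, linear model over 13 pairs). The adipocyte list was higher in the metastasis in 5 of 13 pairs, so these lists do not track normal breast tissue in the primaries alone. That explanation therefore stays open. For a lower share of all non-tumor cells, the endothelial list was set against the immune genes. It was 1.00 ± 1.29 log2 units above them (SD over 13 pairs, exact sign-flip p = 0.0129). Without each pair in turn the difference was at least 0.76 (exact sign-flip p at most 0.0259). Without the 2 pairs with the highest endothelial values, 2.10 and 1.77, it was 0.61 (exact sign-flip p = 0.0518). Those 2 pairs also had the highest blood list (5.63) and lung list (4.67). In the 6 pairs with every organ list and the blood list less than 2 above the own primary the difference was 1.12 ± 0.80 (5 of 6 pairs, exact sign-flip p = 0.0625). In the other 7 pairs it was 0.89 ± 1.67 (5 of 7 pairs, exact sign-flip p = 0.266). Both sides of this comparison were chosen with their results known, the immune genes among lists that fell, so its exact p cannot decide the question. Fibroblast and matrix genes fell by 1.43 and epithelial junction genes rose by 0.50. A lower share of all non-tumor cells therefore stays open as the whole cause or a part of the fall, and the organ of the metastasis is untested.

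CECR2 was higher in 12 of 13 metastases. The CECR2 difference was 0.90 ± 1.46 log2 units above that of the epithelial junction list (10 of 13 pairs, exact sign-flip p = 0.0479), a p close to the threshold. This list is not specific to tumor cells and CECR2 was picked for the series title, so a higher tumor-cell share stays open. Deeper metastasis libraries are argued against by a mean difference of 1.56 ± 1.22 in the 6 pairs with a shallower metastasis library (exact sign-flip p = 0.0312), and host brain tissue by a difference of 1.32 at an equal brain list level (95% interval 0.39 to 2.25, linear model over 13 pairs). Without the 2 pairs with high liver markers the difference was 1.21 (exact sign-flip p = 0.0234), and host tissue of further organs and treatment between the samplings were not tested.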
